A study of Mus musculus with 15 samples.

How the data were processed

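RNA from the colons of 15 male BALB/c mice was measured on 1-colour (Cy3) Agilent arrays carrying circRNA and mRNA features. Each mouse gave 1 array, and the labels placed 5 mice in each of 3 groups: control, colitis and colitis-associated cancer (CAC). The submitters' design text states 30 mice but 5 per group, and 15 samples were analysed here. Replicates are named 1 to 5 within a group, a name only. No slide, scan date or hybridisation batch is given in the labels, so no batch could be tested.

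Total RNA was extracted with TRIzol, and Cy3-labelled cRNA was made with a 1-colour Agilent amplification kit, per the labels' protocols. Arrays were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The values deposited by the authors are 1 number per feature and array on what is taken here as a log2 intensity scale, since they run from 1.22 to 17.37 with no value below 0, a range that neither natural-log nor log10 intensities would give. The centring, the log base, the normalization and the filter on features are not given in the sources used here. Any 2 columns shared between 60.9% and 62.9% of their exact values, which is what quantile normalization over a larger set of features followed by removal of some of them would leave. The table holds 65522 features, no missing value and no column of another sample. If quantile normalization was used, it evened out differences in total signal between arrays. A general rise or fall of RNA per cell would then not be seen. Without background or detection flags, the level at which a feature is distinguishable from background is unknown. Differences from values near the bottom of the scale therefore depend on that floor. The number of arrays limits the precision.

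The features carry IDs with 4 prefixes: mmu_gmr (48936 features), mmu_bmr (11007), mmu_gmi (5141) and mmu_bmi (438). The files do not pair these IDs with genes, and 0 of them occurred among the 49997 genes of the reference table (GRCm38.p6) or its synonyms and accessions. No gene, circRNA or host gene is therefore named, and the meaning of the prefixes was not inferred. Before the data were examined, 31 gene lists, a rule for named genes, separate tests for circRNAs and a comparison of circRNAs with their host mRNAs had been fixed. The lists, the reduction of features to 1 per gene and the host comparison could not be run without names. All features were instead tested together as unnamed features. Several features may measure 1 transcript, so counts of features are not counts of genes.

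The deposited log2 values were used without further scaling. A linear model with the 3 groups was fitted to each feature over all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; 12 residual degrees of freedom), and 3 differences were tested, two-sided: colitis minus control, CAC minus control and CAC minus colitis. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all 65522 features. Adjusted p-values in the text are from this limma fit unless another test is named. Features given by ID followed the rule fixed in advance for circRNA features: the 2 largest rises and the 2 largest falls among called features whose 5 values in one group all lay above the 5 of the other. IDs are printed for CAC against control only, a choice made after the values were seen. The fit was tested on simulated arrays with the same means and spreads, independent noise between features and a small known set of changed features. At each size of change 66 or 67 of the 65522 features were changed. The fit called 89.4% of the 4-fold and 53.7% of the 2-fold changes made in CAC against control. For colitis against control it called 92.4% and 37.3%, and for CAC against colitis 90.9% and 53.7%. At a log2 change of 0.5 it called between 1.49% and 4.48% over the 3 comparisons, and between 3.03% and 5.43% of its calls were unchanged features. The share called depends on how many features change, and features that vary together were not simulated. These values therefore need not carry over to the real comparisons, where many more features were called.

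The position of a mouse between the groups was the projection of its values on the difference between the CAC and control means, over features called in CAC against control, scaled so that the control mean is 0 and the CAC mean is 1. Each axis left out 1 control and 1 CAC array, and control and CAC mice were scored only on axes that did not use them. Positions, array medians and distances to the rest of the group were compared by two-sided exact permutation tests over the 252 assignments of 10 mice, a family of 8 tests. Each ID prefix was set beside 10000 random sets of features matched on mean level. Because colitis and CAC were compared with the same 5 controls, the correlation and covariance of their changes were set beside 20 simulations of unchanged groups, and their overlap beside 20 divisions of the controls, in which colitis was compared with some controls and CAC with the rest.

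The alternatives planned in advance were re-centring on the 75th percentile, quantile normalization, leaving out the lowest 25% of features by mean, 2 variants of eBayes, a fit of only the compared groups, array weights, a 2-fold minimum, leaving out each mouse, and the number in the sample title as a block.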

Results

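The series followed colon RNA through the phases of colitis-associated colorectal cancer in mice. Control mice had plain water over 75 days. Colitis mice were given 3.0% dextran sulfate sodium (DSS), a polymer that damages the colonic epithelium, to drink for 7 days. CAC mice received 12.5 mg/kg of azoxymethane (AOM), a carcinogen of the colon, and from 5 days later repeated courses of 3.0% DSS for 7 days, each followed by 14 days of water. The tissue was colonic mucosa, with the masses, inflamed mucosa and normal mucosa dissected, and each group held 5 mice. Sample titles name intestinal epithelial tissue in control, colitis tissue in colitis and colitis-associated cancer tissue in CAC. The kind of tissue, and the cells in it, may therefore differ with the group in every comparison. The day of sampling of the colitis mice is not given in the sources used here, so the interval from first treatment to sampling, and the age at sampling, may differ between groups.

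The 65522 features had array medians of 6.08 ± 0.05 log2 units in control, 6.11 ± 0.04 in colitis and 6.16 ± 0.04 in CAC (mean ± SD, n = 5 each). Single arrays had medians of 6.004, 6.09, 6.09, 6.12 and 6.11 in control 1 to 5, of 6.08, 6.18, 6.08, 6.11 and 6.09 in colitis 1 to 5, and of 6.10, 6.17, 6.16, 6.20 and 6.17 in CAC 1 to 5. The CAC median exceeded the control median (exact permutation test, p = 0.0238, adjusted p = 0.0476), and it did not differ detectably from that of colitis (exact permutation p = 0.0794, adjusted p = 0.106). Correlations between arrays of 1 group, across features, ran from 0.959 to 0.985 in control, from 0.962 to 0.984 in colitis and from 0.943 to 0.971 in CAC. The closest pair of a group differed by a median of 0.19 log2 units in control and in colitis and 0.25 in CAC. No array was treated as a repeat of another. Among these arrays, CAC mice differed more from one another than control mice did. Their root mean square distance to the rest of their group was 0.61 ± 0.06 log2 units, against 0.46 ± 0.07 in control (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0423). Colitis stood at 0.47 ± 0.08, and the difference of CAC from it narrowly missed the threshold (exact permutation p = 0.0317, adjusted p = 0.0508). The 5 distances of a group are computed from the same 5 arrays and are not independent. The p-values for distances are therefore not a strict test of spread between mice.

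Colitis was compared with control to find the RNAs that changed with DSS. Of the 65522 features, 1704 were called (2.60%), of which 1267 were higher and 437 lower in colitis. The median called rise was 2.28-fold and the median called fall 1.80-fold. A change of at least 2-fold was seen in 927 called features, 788 higher and 139 lower, and at least 4-fold in 225, 210 higher and 15 lower. The largest rise that separated all 5 colitis from all 5 control mice was 7.21 ± 1.46 log2 units (SE; adjusted p = 0.0121), from 6.08 ± 4.35 to 13.30 ± 1.30 (SD, n = 5 each). The controls themselves were split at this feature, with mice 2 and 5 at 10.68 and 10.85 and the other 3 between 1.67 and 3.79. The feature with the largest separated fall fell by 5.22 ± 0.87 log2 units (SE; adjusted p = 0.0029), from 14.53 ± 0.30 in control to 9.32 ± 2.35 in colitis (SD, n = 5 each). In a limma fit of only these 10 arrays 2921 features were called, 1904 higher and 1017 lower, and with array weights 5574, 3029 higher and 2545 lower, so that the share of higher features was 65.2% and 54.3% instead of 74.4%. Leaving out control 3, control 4, colitis 4 or colitis 5 reduced the count to 1017, 1057, 970 or 1015, of which 186, 164, 188 or 213 were lower. The lower features numbered 266 without colitis 1, 259 without colitis 3 and 688 without CAC 3. The 5 values of colitis and the 5 of control did not overlap at 4385 features (6.69%, where chance gives 0.79%), 2744 higher and 1641 lower.

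CAC was compared with control to find the RNAs that changed by the end of the tumour protocol. Here 20580 features were called (31.4%), 12357 higher and 8223 lower in CAC. The median called rise was 1.76-fold and the median called fall 1.84-fold, and 7630 features changed by at least 2-fold (4438 higher, 3192 lower) and 1152 by at least 4-fold (925 higher, 227 lower). The groups did not overlap at 11432 features (17.45%, where chance gives 0.79%). Which direction held more features depended on the scaling. Higher features made up 60.0% of calls as deposited, 55.2% after re-centring on the 75th percentile and 51.5% after quantile normalization. Among changes of at least 2-fold, 4438 were higher and 3192 lower as deposited, and 4125 and 3535 after re-centring on the 75th percentile. Only after quantile normalization did the majority turn, with 3682 higher and 4094 lower.

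**Figure D1:**
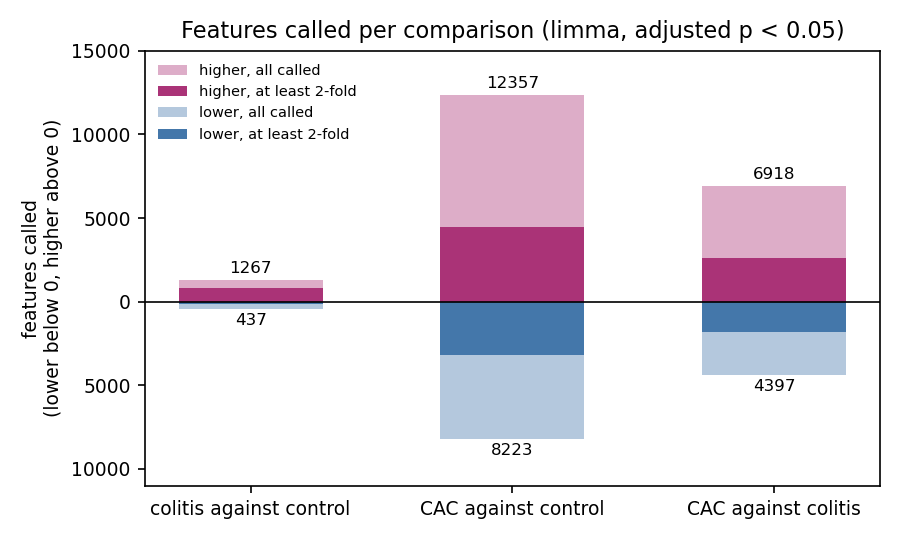
Number of features called in each comparison (limma, adjusted p under 0.05; vertical axis, features), with higher features above 0 and lower features below 0; dark bars are changes of at least 2-fold. CAC against control gave 12357 higher and 8223 lower features, and colitis against control 1267 and 437.

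The largest separated rises in CAC were those of mmu_gmr012067 and mmu_gmr015420. The feature mmu_gmr012067 stood at 2.33 ± 1.41 log2 units in control, 3.98 ± 1.62 in colitis and 11.03 ± 2.42 in CAC (SD, n = 5 each). Its rise in CAC over control was 8.70 ± 1.02 log2 units (SE; adjusted p = 4.06e-05), or 417-fold, and CAC also exceeded colitis by 7.04 ± 1.02 (adjusted p = 0.00114), whereas colitis and control were not told apart (1.66 ± 1.02, adjusted p = 0.516). The rise of mmu_gmr015420 was 8.53 log2 units over control (adjusted p = 4.03e-05), from 2.50 ± 1.42 to 11.03 ± 2.33 (SD, n = 5 each). At both features CAC 3 was far below the other CAC mice, and without it the rises were 9.78 and 9.57 log2 units. Both had similar values in each mouse, so they are not separate observations. Several control values lay close to the bottom of the scale, so these folds depend on the floor. Among the separated falls, the largest were at mmu_bmr019365, which fell by 4.41 ± 0.87 log2 units (SE; adjusted p = 0.00175), and at mmu_bmr001200, which fell by 4.35 ± 0.65 (adjusted p = 0.000256). The feature mmu_bmr019365 was also the largest separated fall in colitis, and it did not differ detectably between CAC and colitis (difference 0.81 ± 0.87 log2 units, SE; adjusted p = 0.55), a difference whose sign turned without colitis 1 (-0.11). The feature mmu_bmr001200 went from 6.96 ± 0.66 in control through 4.72 ± 1.52 in colitis to 2.61 ± 1.18 in CAC (SD, n = 5 each). Its difference between CAC and colitis passed the test (adjusted p = 0.0361), but did not without colitis 1, 2 or 3 or CAC 1, 2 or 5 (limma adjusted p from 0.0545 to 0.09), in a fit of only these groups (0.0766) or with array weights (0.0549). That between colitis and control did not pass (adjusted p = 0.088), but did without colitis 2 (difference -2.81 log2 units, limma adjusted p = 0.0149), without both colitis 2 and CAC 3 (adjusted p = 0.00591) and with array weights (-2.81, 0.00226).

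**Figure D2:**
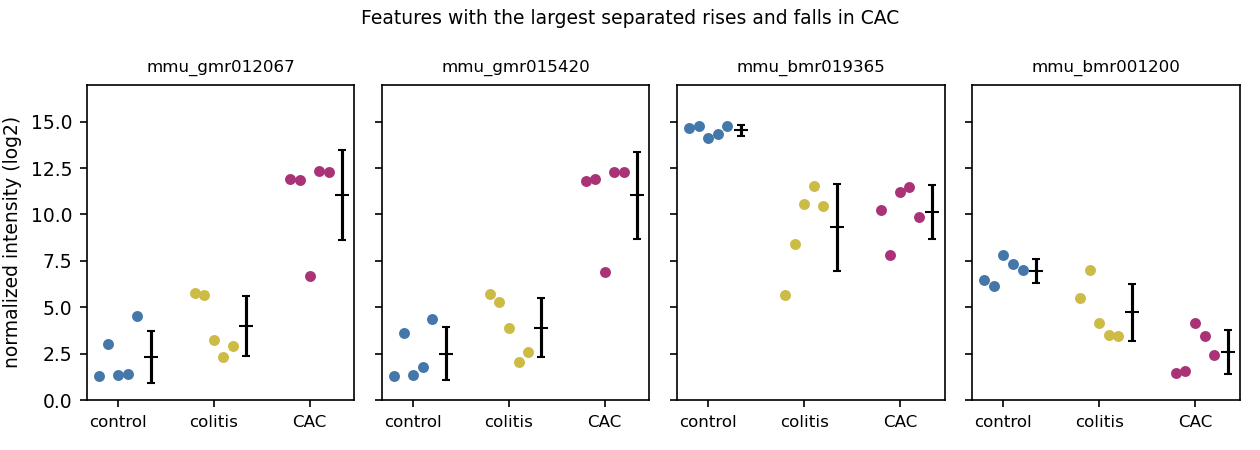
Normalized intensity (log2, vertical axis) of the 4 features with the largest separated rises and falls in CAC against control, for each of the 5 mice per group (points) with the group mean and SD (bars). At mmu_gmr012067 CAC 3 reads 6.71 where the other 4 CAC mice read 11.9 to 12.3.

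CAC was compared directly with colitis to find the RNAs that differed between the tumour protocol and DSS colitis. AOM, the repeated DSS courses, the time to sampling and the tissue dissected may all differ between these groups. Their effects cannot be told apart here. The test called 11315 features (17.3%), 6918 higher and 4397 lower in CAC, 4395 of them by at least 2-fold (2602 higher, 1793 lower). The groups did not overlap at 5786 features (8.83%, where chance gives 0.79%). The largest separated rise was 7.24 log2 units (adjusted p = 0.00144), from 2.73 ± 0.30 in colitis to 9.97 ± 2.94 in CAC (SD, n = 5 each), with CAC 3 at 4.78 and the other CAC mice between 10.75 and 11.98. The feature with the largest separated fall fell by 7.62 ± 1.37 log2 units (SE; adjusted p = 0.00301), from 12.81 ± 1.11 in colitis to 5.19 ± 3.50 in CAC (SD, n = 5 each). At this feature CAC 4 read 11.35 and the other 4 CAC mice between 2.75 and 4.45. The count fell to 7346 in a limma fit of only these 10 arrays. It fell to 6690, 6686 or 7124 without colitis 1, colitis 3 or CAC 2, and rose to 14607 without CAC 3. As for control, the majority of changes of at least 2-fold turned after quantile normalization (2161 higher, 2252 lower). It did not turn after re-centring on the 75th percentile (2434 higher, 1960 lower).

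To find how far the changes of colitis and CAC coincide, their calls against control were compared. Of the 1704 colitis calls, 1468 (86.2%) were called in the same direction in CAC against control, 1141 higher and 327 lower, and 3 in the opposite direction. Independent lists of these sizes would share 239 higher and 54.8 lower features. When the controls were divided, so that the comparisons had no control in common, a mean of 459 features (range over the 20 divisions 259 to 710) were called in the same direction, where independent lists would share a mean of 54.4. A mean of 6.5 (range 0 to 87) were called in the opposite direction. The shared count was 920, 960, 881 or 909 without control 3, control 4, colitis 4 or colitis 5. The 1468 shared features were 7.13% of the CAC calls. Across features the log2 changes in colitis and CAC correlated with r = 0.53, where simulated unchanged groups with shared controls gave a mean of 0.50. That simulated value is set in advance by sharing controls among groups of equal spread, so it cannot be used to judge the 0.53. With divided controls, which share no error of the controls, r was 0.36 (range 0.26 to 0.45). The covariance was 0.158 against 0.0388 in simulation, and 0.124 (range 0.0958 to 0.144) with divided controls. The 1267 features higher in colitis had a median rise of 1.19 log2 units in colitis and of 1.26 in CAC. The 437 lower ones had medians of -0.85 and -0.82. In the direct test 1036 of the features higher in colitis were not called between CAC and colitis, 153 had moved further from control in CAC and 78 had moved back. Of those lower in colitis 350 were not called, 35 had moved further and 52 had moved back. Because these features were chosen for their colitis values against the same controls, both the colitis and the CAC medians are biased away from 0. With divided controls, features called higher in colitis had medians of 1.78 in colitis and 1.68 (range 0.96 to 2.13) in CAC, and those called lower had -1.28 and -0.68 (range -0.94 to -0.20).

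**Figure D3:**
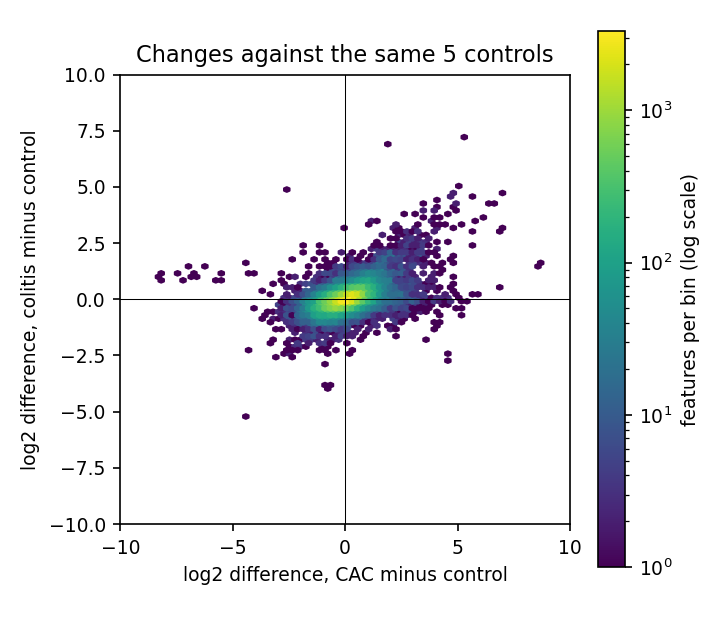
Log2 difference of colitis from control (vertical axis) against that of CAC from control (horizontal axis) for all 65522 features, coloured by the number of features per bin on a log scale. Both axes use the same 5 controls. The covariance was 0.158, where simulated unchanged groups of equal spread with shared controls gave 0.0388.

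Features called in CAC were also followed in colitis. With the controls divided, features called higher in CAC rose there by a median of 1.12 log2 units and differed by 0.28 (range over the 20 divisions 0.14 to 0.41) in colitis. Features called lower fell there by a median of 1.12 log2 units, against a difference of -0.22 (range -0.31 to -0.15) in colitis. Because these features were chosen for their CAC values, the CAC medians are biased away from 0. The sign was the same in colitis for a mean of 78.5% of these features. On an axis from the control mean (0) to the CAC mean (1), colitis mice stood at 0.32 ± 0.09 and control mice, left out of their own axis, at 0.07 ± 0.05 (SD, n = 5 each). Every colitis mouse stood above every control mouse (exact permutation test, p = 0.00794, the smallest this design can give; adjusted p = 0.0317). CAC mice stood at 0.89 ± 0.22, each above every colitis mouse (exact permutation p = 0.00794, adjusted p = 0.0317). CAC 3, at 0.53, was the lowest of them, and the other 4 lay between 0.83 and 1.07.

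**Figure D4:**
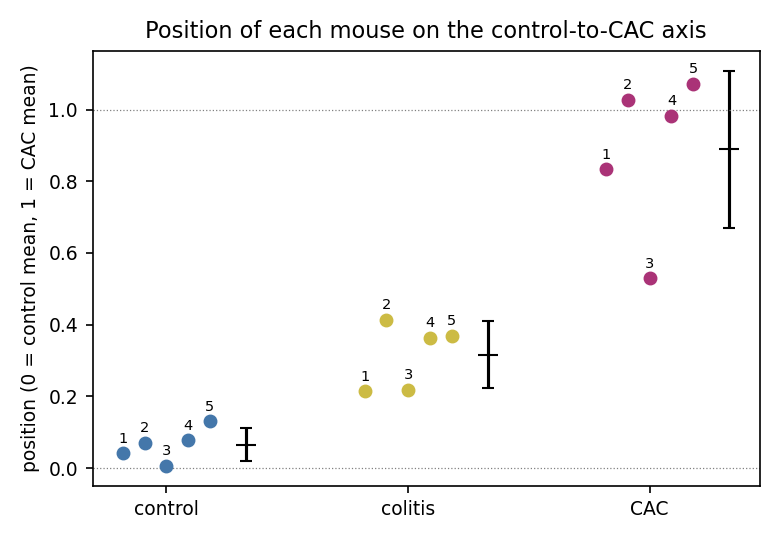
Position of each mouse (points, numbered by replicate) on the axis from the control mean (0) to the CAC mean (1), with the group mean and SD (bars, n = 5). Colitis mice lie between 0.21 and 0.41, and CAC 3 lies at 0.53.

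The calls were counted for each of the 4 ID prefixes. In colitis against control, 972 mmu_gmr features were higher and 373 lower, 237 mmu_bmr features were higher and 44 lower, 55 mmu_gmi features were higher and 20 lower, and 3 mmu_bmi features were called, each of them higher. In CAC against control the counts were 9575 higher and 6027 lower for mmu_gmr, 1883 and 1454 for mmu_bmr, 855 and 681 for mmu_gmi, and 44 and 61 for mmu_bmi. Since dimmer features were called less often, each prefix was set beside 10000 random sets of features matched on mean level. The mmu_gmi features were called less often than matched sets in colitis against control (1.46%, where 95% of matched sets gave 2.16% to 3.00%). They were also below them in CAC against control (29.9% against 30.1% to 32.5%) and in CAC against colitis (15.8% against 16.3% to 18.3%). The mmu_bmr features were called more often than matched sets in all 3 comparisons, with 2.55% against 1.86% to 2.35%, 30.3% against 28.1% to 29.5%, and 17.2% against 15.71% to 16.95%. The mmu_gmr features lay within the range of matched sets in all 3 comparisons. The mmu_bmi features did so against control in colitis and in CAC, and were below it in CAC against colitis (11.87% against 12.56% to 19.41%). Features are not independent replicates, so these ranges describe these arrays only.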

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

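Of the tests in this part, the one of scaling, with the rule for reading it, the one of a sample swap, the reading of the distances of CAC 3 and the one of features separating CAC from colitis were chosen after the result was seen; 3 outlying values were found among 21 sets of 5 values, where chance gives about 1 in 20. The array median of control 1 was 6.004 log2 units, below the 6.09 to 6.12 of the other controls. At mmu_gmr012067 CAC 3 read 6.71, where the other CAC mice read 11.9 to 12.3, and at mmu_gmr015420 it read 6.88 against 11.8 to 12.3. Both features had similar values in each mouse, so their flags are not separate observations. Part of the 21 sets came from features chosen for large changes in these arrays, so the rate of 1 in 20 does not strictly apply.

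CAC 3 lay nearer to colitis than its group did, at 0.53 on the control-to-CAC axis, with a mean correlation across features of 0.956 with the colitis arrays and of 0.950 with the other CAC arrays, and colitis 2 was the highest colitis mouse on that axis, at 0.41. A swap of these 2 is argued against, since colitis 2 correlated more with its own group by 0.0218 and each such correlation was above each of its correlations with CAC, and noise in dim features is argued against for CAC 3, which stayed at 0.482 in the features at or above the median level, where the other CAC mice began at 0.895, while colitis 2, at 0.446 there, was level with colitis 5 at 0.448, so its lead may come from dim features. A colitis sample under a wrong label stays open. CAC 3 lay 0.685 log2 units (root mean square) from the colitis arrays, where no colitis mouse lay over 0.590 from the rest of its group. This distance met the rule set beforehand against a colitis label. CAC 3 also lay 0.695 from the other CAC arrays, where no other CAC mouse lay over 0.646, a smaller excess. The distances place CAC 3 outside both groups, so they do not decide between the labels. Features that separated CAC from colitis by 4-fold were chosen without CAC 3. When colitis mice were left out in turn, CAC 3 reached the range of the other CAC mice at 11.4% to 17.5% of them. The left-out mice reached it at 1.40% to 8.87%, and the lowest value of CAC 3 exceeded the highest of these by less than 2 SD of these. That bound sets values from different fits side by side. Within each fit CAC 3 was above the mouse left out, most narrowly without colitis 2 (16.2% against 8.87%). Each fit scores the same array, so the fits do not settle its label. CAC 3 fell in the colitis range at 36.2% to 47.1%, below the 53.5% to 89.0% of the left-out mice. When the other CAC mice were left out in turn, CAC 3 reached the CAC range at 10.42% to 15.98%, below their 53.3% to 85.5%. It fell in the colitis range at 45.9% to 49.8%, above their 1.97% to 13.1%. Both counts place CAC 3 between the groups. An admixture of control-like RNA stays open, since 2 estimates of the share of CAC-like RNA in CAC 3 differed but their quartiles overlapped. The share came to 66.6% from features lower in CAC (quartiles 43.6% and 89.0%) and to 21.0% from features higher in CAC (quartiles 4.23% and 52.8%). In the other CAC mice the lower features gave 63.9% to 101.6%, a range that holds the value of CAC 3. The higher features gave 115% to 143% in them, so the measure is not a strict share. A milder response in CAC 3, or a piece with less of the mass, was not tested.

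The excess of higher over lower calls in CAC moved with the array medians. With all arrays set to 1 distribution the share of higher calls in CAC against control was 51.5% instead of 60.0%, and with only the 75th percentile aligned it was 55.2%. Unequal medians left by the removal of features after normalization could account for the excess, but a scaling that equalises the arrays would also remove a true excess of rising RNAs, so the explanations cannot be told apart here.

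A chance assignment of the mice to groups is argued against for each count of calls, but not a batch that followed the groups. Among 100 of the 126 splits of the 10 mice, the real one included, 1 split, the real one, reached the count in each comparison. The highest other splits called 400 features against 1704 for colitis and control, 5864 against 20580 for CAC and control, and 3355 against 11315 for CAC and colitis. The latter 2 differed from the real grouping only in that CAC 3 had changed places with control 2 or with colitis 4.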

How the results depend on the processing

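The counting of features without overlap, the fit without both colitis 2 and CAC 3, the shared count with weights, the block or a mouse left out, and leaving out a mouse of the group not compared were added after the data were seen. Calls for colitis against control were 1704, but 2921 in a fit of only the 2 groups, 5574 with array weights, 927 with a 2-fold minimum and 4385 by counting features without overlap. Those for CAC against control were 20580, but 7630 at 2-fold and 11432 without overlap, and those for CAC against colitis were 11315, but 7346 in the fit of 2 groups, 4395 at 2-fold and 5786 without overlap. The features shared by colitis and CAC against control were 1468, but 3747 with array weights, 743 at 2-fold and 874 with the title number as a replicate block. With divided controls they were a mean of 459, of a mean of 659 colitis calls. Title numbers that recur between groups gave no clear pairing of the mice. Correlations of deviations across features were 0.14, -0.06 and 0.11 for same-numbered colitis and control mice. They were 0.10 and -0.02 for CAC and control, and 0.12 and 0.06 for CAC and colitis. Differently numbered mice gave -0.36 to 0.34. The block, which leaves fewer degrees of freedom, called 1175, 14848 and 9269 features. Leaving out 1 of the 15 mice gave 970 (without colitis 4) to 2247 (without CAC 3) calls for colitis against control, 16505 to 22305 for CAC against control, 6686 to 14607 for CAC against colitis, and 881 (without colitis 4) to 1851 (without CAC 3) shared features, with 920, 960 and 909 without control 3, control 4 and colitis 5. Leaving out both colitis 2 and CAC 3 gave 2023, 23577 and 16580 calls. The counts under both rescalings, both eBayes variants and the filter on dim features stayed within 1.5 times the reported ones. The direction of mmu_bmr019365 in CAC against colitis, not called at 0.81, turned to -1.58 under the replicate block and ran from -0.11 to 1.38 when 1 mouse was left out. The differences of the 4 named features otherwise kept direction and side of the threshold in 172 values with a mouse left out and 102 others, except at mmu_bmr001200, where a call was lost in 6 and 2 and gained in 1 and 3, the block among them (colitis against control -3.10, adjusted p = 0.0171). Some settings use fewer mice or features, and the cause of these changes was not tested. For CAC against control the fit of only the 2 groups called 17820 features. The main fit used 1 spread per feature for all 3 groups. The median SD within a group was 0.27 log2 units in control, 0.30 in colitis and 0.37 in CAC. Counts of the 3 comparisons therefore need not be comparable with one another. Without detection flags, signal over background cannot be judged, and in the dimmest 25% of features 0.43% were called in colitis against control, against 3.72% in the brightest 25%. The reduction of features to 1 per gene, the list tests and the host comparison were not run.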

Other observations

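The test of neighbouring IDs below was chosen after the pattern was seen. Within CAC, 24 features spanned at least 256-fold, 15 of them with the prefix mmu_bmr, against 3 in control and 1 in colitis. The 8 features with the largest mean fall in CAC against control, chosen after their values were seen, were called with differences of -6.72 to -8.31 log2 units (adjusted p from 0.00384 to 0.0112). Across the 15 arrays the lowest correlation between any 2 of them was 0.98, so they follow 1 profile and are not 8 separate observations. Their median was 13.3 log2 units in CAC 4, within the 12.2 to 14.6 of the colitis mice, and 3.08, 4.76, 1.72 and 1.47 in CAC 1, CAC 2, CAC 3 and CAC 5. Among controls it was 15.6 and 15.5 in mice 3 and 5 and 9.60, 10.8 and 10.3 in mice 1, 2 and 4.

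Features with a spread of at least 8-fold within a group, at which 1 array stood apart from the other 4, were counted. They were most numerous in CAC 3, where 221 were low and 35 high. Colitis 5 had 147 high, control 1 had 82 high, CAC 4 had 73 high and CAC 1 had 66 high. Features with this spread, with or without an array apart, numbered 540 in control, 569 in colitis and 1489 in CAC. Raw counts are therefore not comparable between groups. The 73 features of CAC 4 had a median level of 6.45 log2 units there and of 2.17, 2.11, 1.76 and 1.71 in CAC 1, CAC 2, CAC 3 and CAC 5.

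Neighbouring ID numbers may measure related transcripts, a hypothesis that bears on how many independent RNAs a count of features stands for. Of 42070 mmu_gmr pairs with consecutive numbers, 22.4% had deviations from the group means that correlated above 0.8 across the 15 arrays, against 0.95% of pairs matched on level. The share was 14.0% at a step of 2, 5.24% at 5, 1.94% at 10 and 0.56% at 100. At consecutive numbers it was 13.3% for mmu_gmi and 9.15% for mmu_bmr. The places of the features on the array were not used here, so neighbouring spots remain open as another source.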
